A study of Mus musculus with 8 samples.

How the data were processed

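Total RNA of primary mouse hepatocytes was measured on 8 whole-transcript gene arrays, 2 for each combination of HO1 genotype (HO1+/+ or HO1-/-) and lentiviral shRNA (scrambled or against HO2), with 300 ng RNA an array per the labels' protocols. Cells were transduced, placed in puromycin after 24 h, and pulsed with dexamethasone after selection, per the labels' protocols. The deposited values are log2 signal intensities per probe set, made by the authors with the robust multi-array average (RMA) in the Bioconductor package affy under R 2.15.0, per the submitters' processing notes, which name neither a chip definition file nor a genome build. The deposited table holds 34760 probe sets, and array medians ran from 7.61 to 7.70 on the log2 scale. No further normalization was applied before the tests.

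Probe sets were joined to genes through the platform table. Of them 21640 carried exactly 1 gene symbol and were used, while 1321 with several symbols and 11799 with none were left out. For the 953 genes with several probe sets the brightest over all 8 arrays was kept, which left 19938 genes. Gene names and neighbourhoods came from the RefSeq table of assembly GRCm38.p6, to which 19855 genes matched by gene ID and 83 did not. Genes without a value in the resulting table were not analysed here.

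Log2 values were fitted with limma (version 3.58.1, R 4.3.3) as 4 group means over all 8 arrays, with 4 residual degrees of freedom and empirical Bayes moderation with a mean-variance trend (11.2 prior degrees of freedom). From this fit came 8 comparisons: HO1 knockout, HO2 knockdown and combined, each against control, combined against HO1 knockout and against HO2 knockdown, the interaction, and each effect averaged over the other. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes tested, and called at an adjusted p under 0.05 with no fold threshold. SE is the moderated standard error of a log2 fold change, and log2 fold changes of array signals understate large differences because dim probe sets carry background signal. The comparisons, thresholds, naming rule, 34 gene lists and all alternatives were set before the data were examined, and the list of Hmox1 neighbours was set by rule (genes within 5 Mb). Of 611 list entries 555 were analysed. Named genes are Hmox1, Hmox2, all core clock genes, the 12 largest changes in each direction among called genes whose arrays do not overlap, and the 4 members with the smallest p in each list, of which the text gives some. Predicted genes and small RNAs, known by their symbols, were left out of the ranking by size of change. For the interaction that ranking had no rule on overlap of arrays.

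Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with a correlation estimated from the data, which 4 residual degrees of freedom estimate poorly. Camera compares a list with all other genes tested. Members were counted past the threshold adjusted over all genes tested and adjusted over the list alone. The lists passing with the preset and the estimated correlation numbered 11 and 2 for HO1 knockout against control, 19 and 9 for HO2 knockdown against control, and 19 and 1 for the interaction.

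The fit was tested on simulated data, with log2 changes of known size added to simulated arrays of the 19938 genes. For HO1 knockout against control, 24%, 94% and 100% of genes changed by 0.25, 0.5 and 1 were called, and 9.31% of the genes called had not been changed. For HO2 knockdown against control the shares were 28%, 94% and 100%, with 11.8% not changed, and for the interaction 0%, 62% and 100%, with 5.77% not changed. Changes of 0.25 were thus mostly missed in these simulations, and the shares not changed were above the nominal 0.05. Each of these sizes was given to 50 genes, far fewer than were called in the data. These shares therefore need not hold for the data, where smaller changes can pass. With 1 list shifted by a known amount, camera called it in all 8 comparisons, and called 2 of the 34 others in combined against HO1 knockout and 0 in each other comparison. Simulated genes varied independently of each other. The simulation therefore cannot show how often camera with the preset correlation calls lists wrongly where genes are correlated. Alternatives covered the variance model, array weights, normalization, dim genes, probe sets per gene, thresholds, the replicate number as a block, and leaving out each array in turn.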

Results

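Gene expression was measured on whole-transcript microarrays in primary mouse hepatocytes, the parenchymal cells of the liver, isolated by collagenase perfusion and a density gradient from male BALB/c mice. The mice either carried both copies of the gene for heme oxygenase 1 (HO1+/+) or were homozygous for its knockout (HO1-/-). Heme oxygenase 1, encoded by Hmox1, is inducible, and heme oxygenase 2, encoded by Hmox2, is constitutive. Both split heme into carbon monoxide, biliverdin and iron. Cells of each genotype received a lentivirus carrying either a scrambled short hairpin RNA (shRNA) or an shRNA against HO2. They were selected with puromycin for 3 days, were given 1 µM dexamethasone for 30 min to set their circadian clocks to a common phase, and were harvested 28 h later. The 8 arrays form 4 groups of 2: control (HO1+/+, scrambled), HO1 knockout (HO1-/-, scrambled), HO2 knockdown (HO1+/+, HO2 shRNA) and combined (HO1-/-, HO2 shRNA). The title of the series places the design in the question of whether carbon monoxide metabolism is needed for circadian transcription. All samples come from a common time after dexamethasone, so levels at that time can be compared and rhythms cannot. The labels call the replicates biological but do not say whether they came from separate animals or cultures, so the p-values measure the spread between these samples. Hepatocyte preparation and genotype cannot be told apart. Of the variance over the 19938 genes tested, 48% lay on a component that separated the genotypes and 36.8% on the next, which separated the hairpins. Replicates correlated across genes with Pearson's r between 0.997 and 0.999, and arrays of different groups with r between 0.975 and 0.989.

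Hmox2 was lower in the arrays with HO2 shRNA, and Hmox1 was not lower in the arrays labelled HO1-/-. The log2 signal of Hmox2 was 11.49 ± 0.11 (SD, n = 2) in control, 11.60 ± 0.0012 (SD, n = 2) in the arrays labelled HO1 knockout, 8.35 ± 0.043 (SD, n = 2) in HO2 knockdown and 9.29 ± 0.044 (SD, n = 2) in combined. With HO2 shRNA the signal fell by 3.14 in HO1+/+ cells (SE 0.065, limma adjusted p = 2.58e-14), to 11.4% of control on the linear scale, and in HO1-/- cells it changed by -2.30 (SE 0.065, adjusted p = 7.54e-13), to 20.3%. The difference between these falls was 0.84 (adjusted p = 3.86e-05), so less Hmox2 was lost in the combined arrays. Hmox1 signal was higher instead. On the log2 scale it was 11.43 ± 0.046 (SD, n = 2) in control, 11.97 ± 0.0082 (SD, n = 2) in the arrays labelled HO1 knockout, 11.55 ± 0.028 (SD, n = 2) in HO2 knockdown and 12.44 ± 0.048 (SD, n = 2) in combined. In the arrays labelled HO1 knockout Hmox1 was therefore 0.54 higher than in control (SE 0.046, adjusted p = 3.36e-07), and in combined 0.88 higher than in HO2 knockdown (adjusted p = 7.34e-10). The exons removed in these mice are not given in the sources used here and a whole-transcript probe set sums signal over the gene. This signal therefore neither bears out nor contradicts the genotype, and every direction given below for HO1 rests on the labels.

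**Figure D1:**
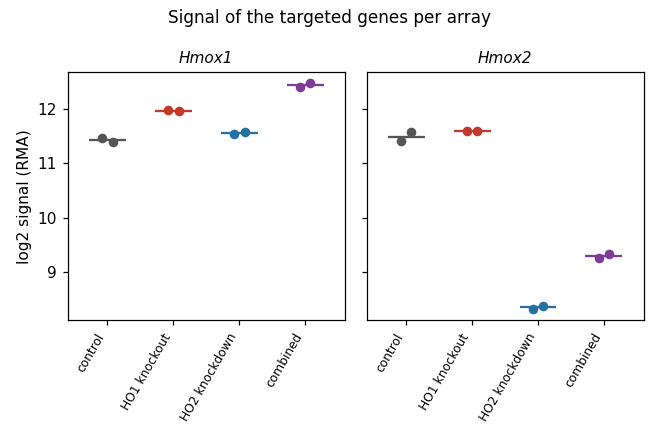
Signal of Hmox1 and Hmox2 on the log2 scale (vertical axis) in each of the 8 arrays, by group (horizontal axis); points are arrays and lines are group means. Hmox2 lies at 8.35 in HO2 knockdown and 9.29 in combined against 11.49 in control, while Hmox1 is higher in both groups labelled HO1-/-.

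The comparison of HO1 knockout with control asks what the HO1 genotype changes where HO2 is intact. Transcripts of macrophages showed the largest rises in the arrays labelled HO1 knockout. Among them were Rnase2a (log2 fold change 5.15, SE 0.11, n = 2 arrays a group as in all comparisons), Ms4a6c (4.80), Adgre1, which encodes the macrophage surface protein F4/80 (4.65), Lyz2, which encodes lysozyme (4.54), the complement receptor gene C3ar1 (4.42) and Cd53 (4.29). Of the Kupffer cell and macrophage markers, 15 of the 20 measured members rose, 1 fell and 4 did not pass the test (16 past it adjusted over the list alone), with a median log2 fold change of 2.05 (camera adjusted p = 6.73e-33, and adjusted p = 0.0339 with an estimated correlation). The complement genes C1qb and C1qc were 3.79 and 3.25 higher. The matrix metalloproteinase gene Mmp8, on the neutrophil list, rose by 4.64, while only 3 of the 12 neutrophil markers did (camera adjusted p = 0.0839). Sinusoidal endothelial markers rose as a list (median 0.14, 5 of 16 rose and 0 fell, 6 past the test adjusted over the list alone, camera adjusted p = 7.22e-06), but not with an estimated correlation (adjusted p = 0.164). Fcgr2b (3.18) and Stab1 (2.20), both also expressed by macrophages, rose most.

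**Figure D2:**
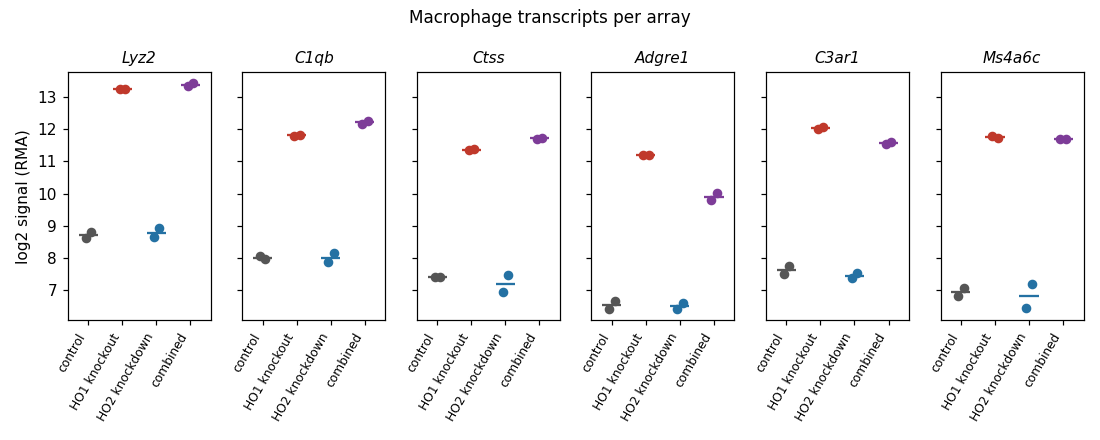
Log2 signal (vertical axis) of 6 macrophage transcripts in each of the 8 arrays, by group (horizontal axis); points are arrays and lines are group means. In every panel the 4 arrays labelled HO1-/- lie above the 4 labelled HO1+/+.

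Transcripts of the acute phase response, whose proteins are made mainly by hepatocytes during inflammation, rose together in the same arrays. Of the acute phase genes, 16 of the 20 measured members rose, 0 fell and 4 did not pass the test (16 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 1.43e-34, and adjusted p = 0.0219 with an estimated correlation). The fibrinogen gene Fgg was 2.35 higher, Orm2 1.86, Orm1 1.59 and Itih4 1.53. The urea cycle gene Arg1, which macrophages also express, rose by 3.77 and Hal, which degrades histidine, by 1.93. The list of amino acid and urea metabolism to which they belong had 5 members up and 3 down of 16 (10 adjusted over the list alone, median 0.063, camera adjusted p = 0.00295, but adjusted p = 0.277 with an estimated correlation). Hepatocyte identity markers rose slightly (10 up and 3 down of 21, 13 adjusted over the list alone, median 0.16, camera adjusted p = 1.8e-05, and adjusted p = 0.0846 with an estimated correlation), with Ambp 1.10 and Ahsg 0.61 higher. Smaller rises past the camera test came from cholesterol synthesis (median 0.17, 6 up and 1 down of 16, with Sqle 0.50 and Insig1 0.45 higher) and glucocorticoid targets (median 0.11, 8 up and 1 down of 17, with Tat 0.62 and Sgk1 0.44 higher). The integrated stress and unfolded protein response also rose (median 0.090, 7 up of 21, with Xbp1 0.35 higher). Adjusted over each list alone, 8, 9 and 11 members passed. These 3 lists had camera adjusted p-values of 1.18e-06, 1.6e-05 and 0.000643, and with an estimated correlation none passed (adjusted p = 0.296, 0.119 and 0.164). Macrophage markers rose in the same arrays (median 2.05). Macrophage RNA could therefore raise genes that macrophages also express, such as Arg1. Its share in the other rises, those of the acute phase genes included, was not tested.

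Interferon-stimulated genes and markers of stellate cells and fibroblasts were lower in the arrays labelled HO1 knockout. Of the interferon-stimulated genes, 0 of the 18 measured members rose, 14 fell and 4 did not pass the test (15 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 2.21e-11). Cxcl10, a chemokine induced by interferon, changed by -1.45, Ifit1 by -0.86 and Oasl2 by -0.77. Of the stellate cell and fibroblast markers, 0 of the 19 measured members rose, 12 fell and 7 did not pass the test (13 adjusted over the list alone, median -0.34, camera adjusted p = 3.87e-08), with Postn at -1.11 and Sparc at -0.90. The macrophage markers moved the opposite way (median 2.05). Neither list passed with an estimated correlation (adjusted p = 0.277 and 0.119). Fatty acid oxidation and PPARA targets had a median of -0.093 (4 of 20 fell, 6 adjusted over the list alone, camera adjusted p = 0.00725, and adjusted p = 0.277 with an estimated correlation), including Pdk4 at -0.53. The largest falls of single genes were those of Obp2a, an odorant binding protein gene (-3.69), Fmr1, whose loss in people causes fragile X syndrome (-2.53), the muscle fructose bisphosphatase gene Fbp2 (-2.11), the retinoic acid hydroxylase gene Cyp26a1 (-1.57) and Cyp21a1 (-1.55). The inflammatory genes went both ways, with Il1a 2.66 and Vcam1 -1.28, and as a list did not pass (median -0.033, camera adjusted p = 0.57).

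Core clock genes differed little between the arrays labelled HO1 knockout and control. Of 19 measured, 1 rose, Nfil3 by 0.25, 1 fell, Bhlhe40 at -0.36, and 17 did not pass, among them the repressor genes Nr1d1 (-0.028, SE 0.069) and Per2 (0.22, SE 0.081) and the activator gene Arntl (-0.17, SE 0.076). The list did not shift (median -0.060, 2 past the test adjusted over the list alone, camera adjusted p = 0.911). In all, 2557 genes differed at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 1121 higher and 1436 lower, and of those at least 2-fold apart 275 were higher and 31 lower. Standard errors of the genes named here lay between 0.037 and 0.15. The count dropped to 1704 without HO1 knockout replicate 1.

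The comparison of HO2 knockdown with control asks what HO2 shRNA changes in HO1+/+ cells. Genes of differentiated hepatocytes were higher and genes of inflammation and cell division lower. Among the largest rises were those of Bhmt, which remethylates homocysteine (4.27, SE 0.14), Cyp4a31 (3.67), the plasma protein gene Hrg (3.54), the drug-metabolising cytochrome gene Cyp3a11 (3.48), the plasminogen gene Plg (3.40) and G6pc, the catalytic subunit of glucose-6-phosphatase (3.04). Of the hepatocyte identity markers, 18 of the 21 measured members rose, 1 fell and 2 did not pass the test (19 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 5.35e-19, and adjusted p = 0.0189 with an estimated correlation). They included the apolipoprotein genes Apoa2 (2.80) and Apoa1 (2.32). The neighbouring genes Phf11c (3.28) and Setdb2 (2.94), the latter a histone methyltransferase gene, were also among the largest rises.

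Several metabolic lists rose with HO2 shRNA, together with the hepatocyte identity markers (median 0.84). Of the 19 lists past camera with the preset correlation in this comparison, 15 were up and 4 down. Not all metabolic lists rose, since those of cholesterol synthesis and glycolysis were lower averaged over genotype, as given below. Gluconeogenic genes had 12 of 14 members up and 1 down (13 adjusted over the list alone, median 0.76, camera adjusted p = 3.39e-10, and adjusted p = 0.0604 with an estimated correlation), with Tat at 2.37 and Pck1, the rate-limiting enzyme of gluconeogenesis, at 2.28. Amino acid and urea metabolism had 13 of 16 up and 0 down (13 adjusted over the list alone, median 1.33), with the urea cycle gene Cps1 at 2.99. Bile acid synthesis and transport had 13 of 17 up and 0 down (13 adjusted over the list alone, median 0.68), with the bile acid importer gene Slc10a1 at 2.13 and Nr0b2 at 2.20. Xenobiotic metabolism had 13 of 18 up and 2 down (15 adjusted over the list alone, median 0.61), with Cyp2b10 at 3.38. Fatty acid oxidation and PPARA targets had 14 of 20 up and 0 down (17 adjusted over the list alone, median 0.37), with Cyp4a10 at 2.69 and Fabp1 at 2.38. Glucocorticoid targets had 11 of 17 up and 0 down (13 adjusted over the list alone, median 0.49), with Igfbp1 at 1.62. For these 5 lists, from amino acid metabolism to glucocorticoid targets, camera gave adjusted p-values of 1.42e-16, 6.15e-12, 1.86e-08, 9.81e-10 and 7.3e-09, and with an estimated correlation 0.0297, 0.0267, 0.0297, 0.0338 and 0.0338. Acute phase genes went both ways (10 up and 4 down of 20, 15 adjusted over the list alone, median 0.16, camera adjusted p = 0.000207, and adjusted p = 0.12 with an estimated correlation).

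Among the falls were those of cell cycle genes and of many chemokine genes. Of the 13 measured Cxcl chemokine genes, 10 fell and 2 rose, Cxcl12 (0.86) and Cxcl17 (0.91). This family, chosen after the results were seen, passed camera (adjusted p = 8.86e-06), but not with an estimated correlation (adjusted p = 0.107). The neutrophil-attracting chemokine genes Cxcl5, Cxcl3 and Cxcl2 changed by -3.65, -3.06 and -2.43, Ccl20 by -2.67, and Nos2, the inducible nitric oxide synthase gene, by -2.46. Of the NF-kB and inflammatory genes, 0 of the 18 measured members rose, 16 fell and 2 did not pass the test (17 adjusted over the list alone, median -0.87, camera adjusted p = 5.23e-15, and adjusted p = 0.0425 with an estimated correlation). All 26 measured cell cycle genes fell, also adjusted over the list alone (26), with a median of -1.08 (camera adjusted p = 7.64e-25, and adjusted p = 0.0297 with an estimated correlation). Among them were the cyclin gene Ccna2 (-1.42), the kinase genes Cdk1 (-1.49) and Plk1 (-1.46) and the proliferation marker Mki67 (-1.46). Interferon-stimulated genes had 14 of 18 down and 0 up (16 adjusted over the list alone, median -0.45, camera adjusted p = 7.23e-05, but adjusted p = 0.435 with an estimated correlation), with Oasl2 at -0.81. Markers of other liver cells moved less. Kupffer cell and macrophage markers had a median of -0.098 (0 up and 4 down of 20, 2 adjusted over the list alone, camera adjusted p = 0.388), stellate cell and fibroblast markers 0.021 (camera adjusted p = 0.965) and cholangiocyte markers -0.10 (camera adjusted p = 0.999). Sinusoidal endothelial markers rose (7 up and 2 down of 16, 9 adjusted over the list alone, median 0.15, camera adjusted p = 0.0121, but adjusted p = 0.317 with an estimated correlation), with Cdh5 at 1.17.

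Core clock genes were higher with HO2 shRNA in HO1+/+ cells, where hepatocyte identity markers rose more (median 0.84) and cell cycle genes fell (median -1.08). Of 19 measured, 12 rose, 1 fell and 6 did not pass (14 passed adjusted over the list alone). Nr1d1, which encodes the heme-binding repressor REV-ERB alpha, was 1.33 higher (SE 0.069, adjusted p = 5.67e-10) and the repressor gene Cry2 0.98 (SE 0.069, adjusted p = 2.16e-08). The output factors Dbp, Tef and Hlf were 0.67, 0.59 and 0.46 higher, the activator gene Clock 0.44 and Ciart 0.46. Per1 and Per2 rose by 0.40 and 0.23, Nr1d2 by 0.22, Rora by 0.19 and Csnk1d by 0.15, and Csnk1e was at -0.17. Values that did not pass were 0.12 for Arntl, 0.16 for Per3, 0.041 for Cry1, -0.17 for Nfil3, 0.13 for Bhlhe40 and 0.11 for Bhlhe41. As a list the core clock genes had a median of 0.23 and passed camera (adjusted p = 1.57e-05), but not with an estimated correlation (adjusted p = 0.16). Targets of CLOCK and BMAL1 through E-boxes, 13 of 17 of which rose and 1 fell (14 adjusted over the list alone, median 0.42), passed with both (adjusted p = 9.71e-08 and 0.0425), although the list shares many members with the core clock genes. Outside the clock itself they included Tsc22d3 (0.84), also a glucocorticoid target, and the glycogen synthase gene Gys2 (1.22). Heme-binding regulators, which share Nr1d1, Nr1d2, Clock and Per2 with the clock list, had 6 of 11 up and 0 down (6 adjusted over the list alone, median 0.23, camera adjusted p = 0.000718, but adjusted p = 0.137 with an estimated correlation), with Cbs 1.07 higher. Of the targets of REV-ERB and ROR elements, only 4 were analysed here and 1 passed (median 0.078, camera adjusted p = 0.388).

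**Figure D3:**
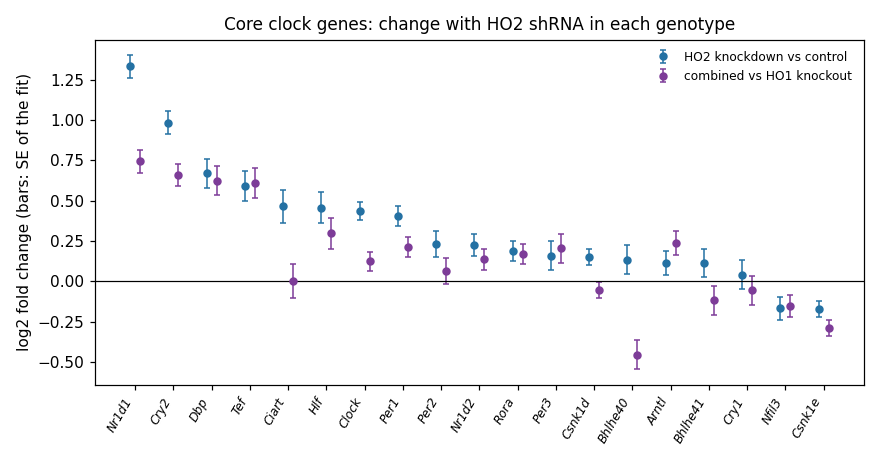
Log2 fold change with HO2 shRNA (vertical axis) of the 19 measured core clock genes (horizontal axis) in HO1+/+ cells (HO2 knockdown vs control) and in HO1-/- cells (combined vs HO1 knockout); points are limma estimates and bars their standard errors. Nr1d1 rose by 1.33 in HO1+/+ and 0.74 in HO1-/- cells.

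With HO2 shRNA, 6620 genes differed in HO1+/+ cells at an adjusted p under 0.05, 3293 higher and 3327 lower. The even balance rests on scaling, since 49.7% of called genes were higher as deposited, 59.4% with arrays centred on their medians and 44.8% after quantile normalization once more. At least 2-fold, 241 were higher and 153 lower. Standard errors of the genes named lay between 0.046 and 0.22. The labels' protocols name 1 HO2 hairpin for these samples, so its effects on other transcripts are part of the comparison.

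The combined arrays were compared with control to show the change with both perturbations. Macrophage transcripts were higher, with Pla2g7 at 4.79 (SE 0.11), Ly86 at 4.75, Lyz2 at 4.66 and Ctss, which encodes cathepsin S, at 4.30. Of the macrophage list 14 of 20 markers rose and 1 fell (15 adjusted over the list alone, median 2.02, camera adjusted p = 8.11e-18, and adjusted p = 0.0436 with an estimated correlation). Hepatocyte identity markers had 18 of 21 up and 1 down (19 adjusted over the list alone, median 0.93, camera adjusted p = 2.45e-18, and adjusted p = 0.0202 with an estimated correlation), and Bhmt, G6pc and Cyp3a11 were 4.29, 3.66 and 3.64 higher. All 26 measured cell cycle genes fell, also adjusted over the list alone (median -0.74, camera adjusted p = 2.45e-18, and adjusted p = 0.0436 with an estimated correlation), with Bub1 at -1.39. Inflammatory genes had 14 of 18 down and 3 up (17 adjusted over the list alone, median -1.03, camera adjusted p = 5.88e-10, but adjusted p = 0.0796 with an estimated correlation). Cxcl5 showed the largest fall (-5.09), followed by Obp2a (-3.91), Cxcl3 (-3.32), the non-classical histocompatibility gene H2-M2 (-3.14) and Cxcl2 (-3.01), and Fmr1 was at -2.44.

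Of 19 core clock genes, 6 rose in the combined arrays against control, 3 fell and 10 did not pass (9 passed adjusted over the list alone, median 0.094), and the list did not pass camera (adjusted p = 0.064). Cry2 (0.79), Nr1d1 (0.72), Dbp (0.56) and Tef (0.45) were higher than in control and Bhlhe40 (-0.81) and Csnk1e (-0.40) lower. Amino acid and urea metabolism (median 1.31, camera adjusted p = 3.26e-17) and bile acid synthesis and transport (median 0.49, camera adjusted p = 1.47e-07) also rose, both with an estimated correlation too (adjusted p = 0.0436 and 0.0436). Among the bile acid genes was Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.70). In these lists 13 of 16 and 11 of 17 members rose and 0 and 1 fell (14 and 13 adjusted over the list alone). The number of genes past the threshold was 5964, 2316 higher and 3648 lower, and at least 2-fold 425 were higher and 177 lower, with standard errors of 0.046 to 0.14 for the genes named.

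HO2 shRNA was next compared within HO1-/- cells, as combined against HO1 knockout. Hepatocyte transcripts again rose, led by Bhmt (4.04, SE 0.14), G6pc (3.50), Mug1 (3.26) and Plg (3.17), and Phf11c was at 3.20. In all 17 of 21 hepatocyte identity markers rose and 0 fell (17 adjusted over the list alone, median 0.58, camera adjusted p = 7.46e-18, and adjusted p = 0.0215 with an estimated correlation). Cxcl5 (-5.00), Cxcl3 (-3.54) and Cxcl2 (-3.21) showed large falls, as did the acute phase genes Saa3 (-3.09), Orm2 (-2.75) and Saa2 (-2.37). Of the inflammatory genes 16 of 18 fell and 1 rose (17 adjusted over the list alone, median -0.83, camera adjusted p = 7.46e-18, and adjusted p = 0.0459 with an estimated correlation). Every measured cell cycle gene (26) fell, also adjusted over the list alone (median -0.70, camera adjusted p = 9.04e-25, and adjusted p = 0.0348 with an estimated correlation). Acute phase genes, which went both ways with HO2 shRNA in HO1+/+ cells, here had 11 down and 6 up of 20 (17 adjusted over the list alone, median -0.23, camera adjusted p = 0.00656, but adjusted p = 0.22 with an estimated correlation). Kupffer cell and macrophage markers went both ways (5 up and 4 down, 10 adjusted over the list alone, median 0.039, camera adjusted p = 0.496), with Adgre1 at -1.29 and Vsig4, a gene of resident Kupffer cells, at 1.35. Interferon-stimulated genes had 7 up of 18 (7 adjusted over the list alone, median 0.29, camera adjusted p = 0.000565, but adjusted p = 0.467 with an estimated correlation), with Ifit3 at 1.21.

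Among core clock genes in HO1-/- cells, 7 rose with HO2 shRNA, 2 fell and 10 did not pass (10 passed adjusted over the list alone). Nr1d1 rose by 0.74, Cry2 by 0.66, Dbp by 0.62, Tef by 0.61, Hlf by 0.30, Arntl by 0.24 and Per1 by 0.21, and Bhlhe40 was at -0.45 and Csnk1e at -0.29. As a list they passed camera (median 0.14, adjusted p = 0.0371), but not with an estimated correlation (adjusted p = 0.467). Genes of cholesterol synthesis fell, with 11 of 16 down and 0 up (11 adjusted over the list alone, median -0.39, camera adjusted p = 1.64e-08, but adjusted p = 0.215 with an estimated correlation), among them Dhcr7 (-0.71) and the regulator gene Srebf2 (-0.67). The threshold was passed by 4587 genes, 2031 higher and 2556 lower, and at least 2-fold by 181 higher and 117 lower (standard errors of the genes named 0.046 to 0.16).

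The HO1 genotype was compared under HO2 shRNA as combined against HO2 knockdown. Macrophage transcripts rose here as well, with Ms4a6c at 4.86 (SE 0.15), Lyz2 at 4.60, Ctss at 4.51, the RNA-sensing receptor genes Tlr7 at 4.40 and Tlr13 at 4.16, and C1qb at 4.19. Of the Kupffer cell and macrophage markers 15 of 20 rose and 0 fell (17 adjusted over the list alone, median 2.00, camera adjusted p = 1.06e-20, but adjusted p = 0.127 with an estimated correlation). Obp2a (-4.66) and Fmr1 (-2.68) were again among the largest falls, as was Cyp4a31 (-2.27). Fatty acid oxidation and PPARA targets had 18 of 20 down and 0 up (18 adjusted over the list alone, median -0.37, camera adjusted p = 7.81e-09, but adjusted p = 0.127 with an estimated correlation), with Cyp4a10 at -1.54 and Ehhadh at -1.08. Cell cycle genes were higher than in HO2 knockdown (16 up and 1 down of 26, 19 adjusted over the list alone, median 0.32, camera adjusted p = 9.64e-08, but adjusted p = 0.28 with an estimated correlation), with Mki67 at 1.04. Core clock genes were lower, 8 down and 1 up of 19 (10 adjusted over the list alone, median -0.14, camera adjusted p = 0.00839, but adjusted p = 0.455 with an estimated correlation). Lower members were Bhlhe40 at -0.95, Nr1d1 at -0.62, Ciart at -0.49, Clock at -0.37 and Cry2 at -0.19. Acute phase genes did not shift as a list (median -0.022, 5 up and 5 down, 10 adjusted over the list alone, camera adjusted p = 0.831).

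Under HO2 shRNA the genotypes differed in 6775 genes, 2591 higher and 4184 lower in the combined arrays, and at least 2-fold in 275 higher and 50 lower, and the genes named had standard errors of 0.046 to 0.22. The split depends on scaling, since 38.2% of called genes were higher as deposited, 27.1% with arrays centred on their medians and 47.7% after quantile normalization once more. The count was 3826 without HO2 knockdown replicate 1, 4485 without combined replicate 1 and 4072 without combined replicate 2.

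The interaction asks whether the change with HO2 shRNA differed between the genotypes, and a negative value means a lower change in HO1-/- than in HO1+/+ cells. HO2 shRNA left 20.3% of the Hmox2 signal in HO1-/- cells and 11.4% in HO1+/+ cells. Where a change was smaller in HO1-/- cells, a weaker knockdown and a different response therefore cannot be told apart. Arg1, Ccl12 and several acute phase genes were among the lowest values. Arg1 was at -3.06 (SE 0.15, adjusted p = 1.2e-08), the chemokine gene Ccl12 at -2.27, Lrg1 at -2.10, Fgg at -2.10 and Saa4 at -1.79. Of the acute phase list 17 of 20 genes passed below 0 and 0 above (20 adjusted over the list alone, median -0.84, camera adjusted p = 4.01e-29, and adjusted p = 0.0305 with an estimated correlation). Interferon-stimulated genes were among the highest, with Ifi44l at 1.95, Ifit3 at 1.67 and Oasl2 at 1.57, and there 13 of 18 passed above 0 and 0 below (17 adjusted over the list alone, median 0.62, camera adjusted p = 1.07e-12, but adjusted p = 0.234 with an estimated correlation). The antigen presentation gene Cd74 was at 1.62. Cell cycle genes, which fell in both genotypes, fell less in HO1-/- cells (14 of 26 passed above 0, 22 adjusted over the list alone, median 0.38, camera adjusted p = 5.32e-11, but adjusted p = 0.157 with an estimated correlation), with Mki67 at 0.84. Among core clock genes 4 passed, all below 0, namely Nr1d1 (-0.59, SE 0.097, adjusted p = 0.000959), Bhlhe40 (-0.59), Cry2 (-0.32) and Clock (-0.31). The rise of Nr1d1, Cry2 and Clock with HO2 shRNA was smaller in HO1-/- cells. Adjusted over the list alone 6 passed, the list median was -0.16 (camera adjusted p = 0.00309, but adjusted p = 0.295 with an estimated correlation). Values that did not pass included Dbp (-0.046), Tef (0.021), Per1 (-0.19), Per2 (-0.17) and Ciart (-0.46).

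Fatty acid oxidation and PPARA targets (8 of 20 passed below 0 and 0 above, 12 adjusted over the list alone, median -0.22, with Cyp4a10 at -1.49) and glucocorticoid targets (5 of 17 passed below 0 and 0 above, 7 adjusted over the list alone, median -0.16, with Dusp1 at -0.53) rose less with HO2 shRNA in HO1-/- cells. Both lists passed camera (adjusted p = 1.17e-05 and 9.34e-06), but not with an estimated correlation (adjusted p = 0.157 and 0.157). An interaction was called for 2442 genes, 932 above 0 and 1510 below, of which 104 were at least 2-fold, with standard errors of 0.053 to 0.32 for the genes named. The share above 0 was 38.2% as deposited, 50.4% after quantile normalization once more and 27.3% with arrays centred on their medians, so the balance of directions is not settled. The count was 4745 without control replicate 2, 1526 without HO1 knockout replicate 1, 1301 without HO2 knockdown replicate 1, 1365 and 1349 without combined replicate 1 and 2, and 1359 without the mean-variance trend.

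Averaged over the hairpins, the arrays labelled HO1-/- had higher macrophage transcripts (17 of 20 markers up and 1 down, 18 adjusted over the list alone, median 2.09, camera adjusted p = 3.63e-25, but adjusted p = 0.0985 with an estimated correlation). The largest rises were those of Ms4a6c (4.83, SE 0.11), Ms4a6d (4.62), Lyz2 (4.57) and Pla2g7 (4.47). Obp2a was at -4.17, Fmr1 at -2.61 and Fbp2 at -1.76. Lists lower on average included fatty acid oxidation and PPARA targets (18 of 20 down, 19 adjusted over the list alone, median -0.24, camera adjusted p = 2.97e-08, but adjusted p = 0.0994 with an estimated correlation), with Pdk4 at -0.53. Heme-binding regulators were lower too (8 down and 1 up of 11, 10 adjusted over the list alone, median -0.22, camera adjusted p = 0.0434, but adjusted p = 0.346 with an estimated correlation), with the guanylate cyclase subunit gene Gucy1b1 at -0.51. Biliverdin reductase A, the next enzyme of heme breakdown, was higher (Blvra, 0.67), Blvrb was lower (-0.24) and Alas1, the rate-limiting enzyme of heme synthesis, was lower (-0.43). Heme breakdown and transport (camera adjusted p = 0.329) and heme synthesis (camera adjusted p = 0.054) did not pass as lists. The average HO1 effect was called for 6141 genes, 1866 higher and 4275 lower, but of those at least 2-fold 244 were higher and 22 lower (standard errors 0.032 to 0.11 for the genes named). The share higher among called genes was 30.4% as deposited, 39.3% after quantile normalization once more and 23.5% with centred arrays.

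Averaged over genotype, Bhmt (4.16, SE 0.097), Cyp3a11 (3.31), Plg (3.29) and G6pc (3.27) rose with HO2 shRNA, and Cxcl5 (-4.33), Cxcl3 (-3.30) and Saa3 (-2.39) fell. Core clock genes had 12 up and 2 down of 19 (16 adjusted over the list alone, median 0.18, camera adjusted p = 0.000296, but adjusted p = 0.228 with an estimated correlation). Their largest rises were those of Nr1d1 at 1.04 (SE 0.049), Cry2 at 0.82, Dbp at 0.65 and Tef at 0.60. Glycolysis genes had 8 down and 2 up of 14 (11 adjusted over the list alone, median -0.18, camera adjusted p = 0.0152, but adjusted p = 0.228 with an estimated correlation). Pfkl was at -0.71 and the glucose transporter gene Slc2a2, itself characteristic of hepatocytes, at 2.21. Cholesterol synthesis had 11 down and 0 up of 16 (12 adjusted over the list alone, median -0.32, camera adjusted p = 6.52e-06, but adjusted p = 0.277 with an estimated correlation), with Fdps at -0.57. Of the genes of iron handling the exporter gene Slc40a1 rose by 0.95 and Tfr2 by 0.51, and of the heme synthesis genes Fech rose by 0.43 and Alad was at -0.35, with neither list past camera (adjusted p = 0.178 and 0.695). The average HO2 effect was called for 6678 genes, 3289 higher and 3389 lower, and at least 2-fold for 185 higher and 117 lower (standard errors 0.033 to 0.10 for the genes named).

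**Figure D4:**
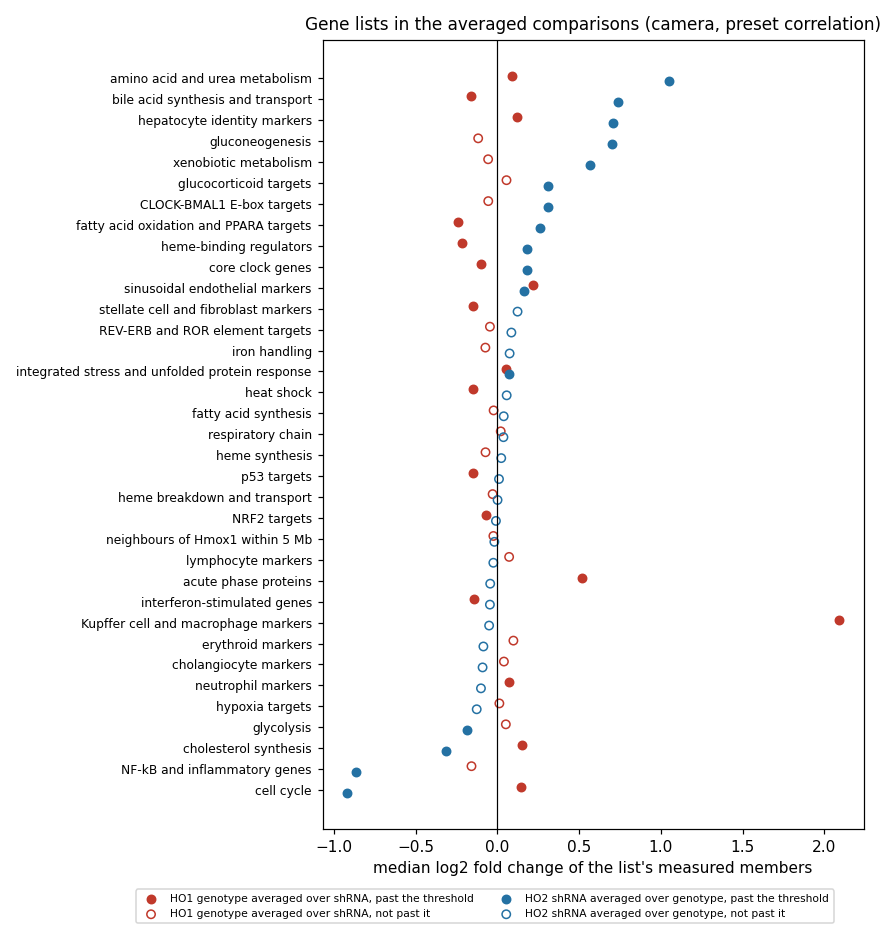
Median log2 fold change (horizontal axis) of each of the 35 gene lists (vertical axis) for the HO1 genotype averaged over hairpins (red) and HO2 shRNA averaged over genotypes (blue); filled points passed camera with a preset correlation and open points did not. The macrophage list stands at 2.09 for HO1 and the cell cycle list at -0.92 for HO2 shRNA.

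The remaining lists moved little in the averaged comparisons. For HO1 genotype and HO2 shRNA respectively, the medians were -0.070 and -0.0094 for NRF2 targets (camera adjusted p = 0.0341 and 0.945), -0.024 and 0.038 for fatty acid synthesis (0.984 and 0.945), 0.020 and 0.037 for the respiratory chain (0.152 and 0.191). They were 0.012 and -0.13 for hypoxia targets (0.778 and 0.154), -0.15 and 0.056 for heat shock genes (0.0167 and 0.178), and -0.15 and 0.0094 for p53 targets (0.0167 and 0.242). For markers of other cells they were 0.040 and -0.091 for cholangiocyte markers (0.283 and 0.945), 0.071 and -0.025 for lymphocyte markers (0.162 and 0.945), 0.098 and -0.086 for erythroid markers (0.15 and 0.606), and -0.025 and -0.019 for the 107 measured genes within 5 Mb of Hmox1 (0.961 and 0.945). Of these, NRF2 targets, heat shock genes and p53 targets passed as lower in the arrays labelled HO1-/-, none with an estimated correlation (adjusted p = 0.34, 0.248 and 0.4). Individual members included Srxn1 at -0.48 and Slc7a11 at -0.70 for HO2 shRNA and Mdm2 at -0.33 for HO1.

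Each effect could be estimated from separate arrays, though the labels do not say whether these came from separate hepatocyte preparations. A difference between preparations could therefore recur in both estimates for HO1 genotype. Across the 19938 genes, the log2 fold changes for HO1 genotype without and with HO2 shRNA correlated with Pearson's r = 0.718 and Spearman's rho = 0.326. Those for HO2 shRNA in HO1+/+ and HO1-/- cells did with r = 0.666 and rho = 0.377, where genes are not independent replicates. For HO1, 698 genes rose and 828 fell in both estimates, where independent lists would share 146 and 301, and 166 went opposite ways. For HO2 shRNA, 1466 rose and 1465 fell in both, against 335 and 427, and 169 went opposite ways. The effects of HO1 knockout and HO2 knockdown, both against control, were little alike (r = 0.0806, rho = 0.134). These comparisons share the 2 control arrays, and simulated unchanged groups against such controls gave r = 0.5. The covariance was 0.00918 against a simulated 0.00411, a difference of 0.00507. The simulation gave controls the spread fitted over all groups. Control replicates differed most (median absolute difference 0.108, against 0.0674 to 0.078 in the other groups), so the simulated value may be too low. Both comparisons called 365 genes up and 493 down, where independent lists would share 185 and 240. They called 593 in opposite directions, which is also more than independent lists would give, so the overlap is not an excess of agreement alone. Part of the excess in shared directions may come from the shared controls, which are too few to split.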

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

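The interaction tests were planned before the data were examined. The explanations tested only after the result was seen are those of resident Kupffer cells alone, fewer non-hepatocyte cells, swapped labels and Hmox1 from macrophages, and the marker lists for the checks were also chosen after seeing the data. After values had been seen, the test of fewer non-hepatocyte cells was changed from the medians of 4 marker lists (macrophage -0.051, endothelial 0.16, stellate 0.12 and cholangiocyte -0.091) to their pooled median. A minimum of 3 resident Kupffer cell genes was also added then, and without it the values would have argued against resident Kupffer cells alone. What singles out each value in this part is a difference between groups, namely that the change with HO2 shRNA differed between the genotypes by the interaction test, which 2442 genes passed. Hmox2 itself was lowered less in HO1-/- cells, so a smaller change there cannot be told apart from a weaker knockdown.

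Macrophage transcripts were higher in all 4 arrays labelled HO1-/-, and Lyz2 stood at 8.72 in control and 13.25 in HO1 knockout, C1qb at 8.02 and 11.81, and Ctss at 7.42 and 11.36. Lyz2 went from percentile 58 of all genes in control to 99.6 in HO1 knockout, and Adgre1 from 21.5 to 91.8. A further 28 macrophage genes were chosen after that rise was seen, 5 of them above the median gene in control. Averaged over hairpins 92.9% of them rose (median 2.1). They widen the pattern without testing whether macrophages were present in the HO1-/- cultures, and which cells the density gradient removed was not measured. Whether these were resident Kupffer cells carried over could not be told, because only Clec4f and Vsig4 of the resident markers stood above the dim genes on average (median -0.557 in HO1 knockout against control, 0.415 in combined against HO2 knockdown), while the dimmer Cd5l went the other way, from 6.12 in control to 7.52 in HO1 knockout. Of the 35 ways to split the 8 arrays into 4 and 4, 2 gave at least the 819 genes of the genotype split in a fit of 2 groups, the other being the hairpin split (2852), which follows the other factor of the design, and the 33 that follow neither factor gave 0 in limma (at most 4097 at an unadjusted p under 0.05, against 3586 for genotype). Because the only larger split is a designed one, this share does not settle whether chance is excluded, and differences in macrophage content by genotype or by preparation stay possible too.

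Hepatocyte transcripts were higher and cell cycle and inflammatory transcripts lower with HO2 shRNA. A loss of non-hepatocyte cells would lower their markers. The pooled median of 64 markers of 4 other cell types was 0.0589 (bootstrap SE 0.046), against 0.705 for hepatocyte identity markers. The pooled markers thus did not fall as that explanation predicts. Some of them were dim in control, such as Adgre1 at percentile 21.5 of all genes and Cd5l at 15.6, while Lyz2 stood at 58. Dim markers have little room to fall, so the pooled median cannot exclude a loss of cells whose markers were dim. An off-target effect of the hairpin could not be tested, since the labels name 1 HO2 hairpin. The hairpin split alone of 35 gave 2852 genes, the next highest, the genotype split, gave 819, and the 33 of neither factor gave 0. At an unadjusted p under 0.05 in limma, the hairpin split gave 5116 and splits of neither factor at most 4097. Splits of neither factor keep both designed effects in their spread, so these counts do not settle whether chance is excluded. A biological effect of lower Hmox2 stays possible beside the effects of that hairpin.

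Hmox1 signal was not lower in the arrays labelled HO1-/- (0.71 averaged over hairpins). Swapped genotype labels would put Hmox1 lower in the arrays labelled HO1+/+, which is the direction seen. The test asked for at least 1, and 0.7131 misses that, with Hmox1 at percentile 93.5 of all genes in control. That cut was set after the result was seen, so missing it does not count against a swap. Swapped and correct labels cannot be told apart because a transcript still made from the disrupted allele, whose deleted part is not given, would keep the signal up under either. Macrophages that express Hmox1 would raise it where macrophage genes rise. Those outside the main list did so in HO1 knockout against control (median 2.13) and combined against HO2 knockdown (2.01). Between HO1 knockout and combined Hmox1 rose by 0.4655 while these genes had a median of -0.0674, so their median did not go with that rise. Single macrophage genes went both ways there, C1qb from 11.81 to 12.21 and Adgre1 from 11.20 to 9.91. Both these groups hold macrophage transcripts, so this test cannot decide whether macrophages brought the difference between genotypes. The interaction for Hmox1 was 0.34. Readers should take the direction of each HO1 comparison from the labels only.

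Acute phase genes had interaction values below 0: Fgg (-2.10), Lrg1 (-2.10), Saa4 (-1.79), Orm2 (-1.76), Orm1 (-1.72), Saa2 (-1.66), Saa3 (-1.41) and Itih4 (-1.16). Among genes of metabolism and plasma proteins the values below 0 were those of Arg1 (-3.06), Hal (-0.96), Cps1 (-0.68), Tat (-0.54), Hrg (-0.96), Cyp4a10 (-1.49), Cyp4a31 (-1.44), Cyp2b10 (-0.79), Ehhadh (-1.07), Fabp1 (-0.65), Nr0b2 (-0.59), Dhcr7 (-0.40), Ahsg (-0.46), Ambp (-0.36), Alas1 (-0.32), Fech (-0.52), Tfr2 (-0.64), Dusp1 (-0.53) and Xbp1 (-0.29). Values above 0 were those of Cyp7a1 (1.06), Fdps (0.33), Alad (0.43), Slc40a1 (0.62) and Fbp2 (0.70). Core clock genes gave Nr1d1 (-0.59), Bhlhe40 (-0.59), Cry2 (-0.32) and Clock (-0.31). Chemokine and adhesion genes gave Ccl12 (-2.27), Cxcl5 (-1.34), Cxcl2 (-0.78), Ccl20 (0.98), Cxcl10 (0.83) and Vcam1 (0.91), and interferon-stimulated genes Ifi44l (1.95), Ifit3 (1.67), Oasl2 (1.57) and Ifit1 (1.28). Genes expressed by macrophages and other leukocytes went both ways, with Rnase2a (-1.98), Adgre1 (-1.25), Fcgr2b (-1.21) and Mmp8 (-0.70) below 0 and Vsig4 (1.37), Cd74 (1.62), C1qc (0.66), Tlr7 (0.61), Ly86 (0.58), Ctss (0.56) and C1qb (0.40) above. Cell cycle genes gave Mki67 (0.84), Cdk1 (0.78), Ccna2 (0.74), Plk1 (0.57) and Bub1 (0.45), and stellate cell genes Sparc (0.72) and Postn (0.48). The remaining named genes were H2-M2 (-1.76), Obp2a (-0.98) and Hmox2 (0.84). Gene lists past camera for the interaction, with medians above 0, were interferon-stimulated genes (0.62), cell cycle (0.38) and stellate cell and fibroblast markers (0.28). Those below 0 were acute phase proteins (-0.84), core clock genes (-0.16), CLOCK-BMAL1 E-box targets (-0.16), heme-binding regulators (-0.17), iron handling (-0.22), NRF2 targets (-0.15), gluconeogenesis (-0.13), fatty acid synthesis (-0.11), cholesterol synthesis (-0.13), fatty acid oxidation and PPARA targets (-0.22), bile acid synthesis and transport (-0.12), xenobiotic metabolism (-0.14), amino acid and urea metabolism (-0.071), glucocorticoid targets (-0.16), p53 targets (-0.15) and hepatocyte identity markers (-0.14). Of these lists only acute phase proteins passed with an estimated correlation (adjusted p = 0.0305).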

How the results depend on the processing

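All alternatives here were set before the data were examined. No called gene, list or correlation given here changed sign under them, but the share of called genes that were higher crossed 50% with scaling. It went from 49.7% as deposited to 59.4% with centred arrays for HO2 knockdown against control, from 49.3% to 53.8% for averaged HO2, and from 38.2% to 50.4% after quantile normalization for the interaction. The count of called genes stayed within 1.5 times the reported value in all 8 comparisons with array weights, robust variance estimates, quantile normalization once more, centred arrays, fewer dim genes, the mean of a gene's probe sets and, in the 5 pairwise comparisons, only the arrays compared. The same held with the replicate number as a replicate block, which gave 2501, 6431, 5871, 4491, 6563, 2327, 5999 and 6612 genes in the order HO1 knockout, HO2 knockdown and combined against control, combined against HO1 knockout and against HO2 knockdown, interaction, averaged HO1 and averaged HO2. Replicates of equal number did not pair, with correlations between groups from -0.261 to 0.122 and 1 of 6 over 0.1. In that order, counts at an absolute log2 fold change of at least 1 were 306, 394, 602, 298, 325, 104, 266 and 302, which is fewer by construction. At an unadjusted p of 0.001 they were 1656, 3924, 3950, 3011, 3610, 1312 and 3612 without the averaged HO2 comparison. For HO1 knockout against control and the interaction, an unadjusted p of 0.05 gave 4680 and 5629, and every probe set tested on its own 1622 and 1287. The interaction had 1359 genes without the trend and 3791 at an adjusted p of 0.1. Leaving out each array in turn, with the lone array of its group assumed to vary like the others, gave 1704 to 2937 for HO1 knockout against control, 3826 to 8253 for combined against HO2 knockdown and 1301 to 4745 for the interaction. The cause of these shifts was not tested.

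At an absolute log2 fold change of at least 1, Hmox1 no longer passed in the averaged HO1 comparison (0.7131), HO1 knockout against control (0.543), averaged HO2 (0.2954), combined against HO1 knockout (0.4655) and against HO2 knockdown (0.8832), interaction (0.3402) and HO2 knockdown against control (0.1253), nor Hmox2 in averaged HO1 (0.5236), combined against HO2 knockdown (0.9413) and interaction (0.8355). The interaction for Hmox1 was also lost without the trend (0.3402). The small change of Hmox1 in HO2 knockdown was lost without the trend, in the groups compared alone, with the replicate block, with array weights and with every probe set (all 0.1253), and after quantile normalization (0.08351). It ranged from 0.09258 to 0.158 over left-out arrays and passed only without control replicate 1 (adjusted p = 0.0479), with adjusted p from 0.0539 to 0.202 without each of the others.

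Gene lists depended on the test. In the same order of comparisons 2, 9, 5, 6, 0, 1, 0 and 8 lists passed with an estimated correlation, and with the mixed form of fry 33, 34, 32, 33, 34, 34, 33 and 33. Directional fry gave 25 for combined against control and 24 for combined against HO2 knockdown. Without the dimmer genes 12 lists passed for combined against HO1 knockout and 7 for the interaction. Spearman correlations were 0.326 for the HO1 effect, 0.3768 for the HO2 effect and 0.1338 between the effects. Within the replicate block, replicate 1 alone gave 0.5577, 0.5155 and 0.1515, and replicate 2 alone 0.1541 between the effects. Without dimmer genes the correlation between the effects was 0.08675, and over left-out arrays 0.05813 to 0.1547.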

Other observations

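The gene families in this part were chosen only after the results were seen, so their tests are not independent of the data that led to them, while predictions for the hypotheses at its end were written before their tests were run. Coagulation factors, most of them made by hepatocytes, rose with HO2 shRNA. Averaged over genotype, 12 of the 18 measured rose and 2 fell (median 0.63, camera adjusted p = 7.56e-10, and adjusted p = 0.0228 with an estimated correlation). The kininogen gene Kng1 was 0.98 higher, F12, which starts the contact pathway, 1.63, F13b 1.23 and the antithrombin gene Serpinc1 0.98, while F13a1, expressed by macrophages, was at -0.45. Their rise was smaller in HO1-/- cells, where Hmox2 was also lowered less. In the interaction 7 of 18 passed below 0 and 0 above (median -0.29, camera adjusted p = 7.23e-07, and adjusted p = 0.0461 with an estimated correlation), lowest for F9 (-1.15). Cytochromes of the Cyp2 family rose as well (23 up and 2 down of 44, median 0.24, camera adjusted p = 5.91e-10, and adjusted p = 0.035 with an estimated correlation), with Cyp2a12 at 2.78, Cyp2j5 at 2.42, Cyp2c39 at 2.05 and the vitamin D 25-hydroxylase gene Cyp2r1 at -0.63. The fatty acid hydroxylase genes of the Cyp4a family, which PPARA controls, differed most between genotypes, since all 5 measured had an interaction below 0 (median -1.49, camera adjusted p = 1.12e-07, and adjusted p = 0.0461 with an estimated correlation). Cyp4a12a and Cyp4a12b, which are higher in male liver, rose with HO2 shRNA in HO1+/+ cells (1.05 and 0.92) and were at -0.76 and -0.75 in HO1-/- cells. Probes of close relatives within the Cyp2 and Cyp4a families can share signal, so members do not count as independent.

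Toll-like receptor genes were higher in the arrays labelled HO1-/-, averaged over hairpins (6 up and 0 down of 10, median 0.59, camera adjusted p = 2.11e-07, and adjusted p = 0.0425 with an estimated correlation). Macrophage markers moved with them in the same comparison (median 2.09), and Tlr7, Tlr13, Ms4a6c and C1qb are themselves expressed by macrophages. The receptor genes that rose were Tlr7 (4.10), Tlr13 (3.92), Tlr8 (3.26), Tlr1 (1.68), Tlr9 (0.67) and Tlr6 (0.50), while Tlr4 (0.091), Tlr3 (-0.088) and Tlr2 (-0.089) did not pass. The Ms4a family had 7 up and 2 down of 19 (camera adjusted p = 2.24e-06, but adjusted p = 0.0592 with an estimated correlation). Complement components had 7 up and 4 down of 17 (camera adjusted p = 0.00483, but adjusted p = 0.0632 with an estimated correlation), with the properdin gene Cfp at 2.96. Genes of the histocompatibility class II pathway had 4 up and 0 down of 9 (camera adjusted p = 0.000498, but adjusted p = 0.135 with an estimated correlation), with H2-Aa at 0.89. Major urinary proteins, pheromone carriers made by male liver, were lower in these arrays (3 of 3, camera adjusted p = 0.00134, but adjusted p = 0.0632 with an estimated correlation), with Mup3 at -1.14. Collagens had 7 up and 2 down of 44 (camera adjusted p = 0.00357, but adjusted p = 0.502 with an estimated correlation). Cxcl chemokines fell with HO2 shRNA (9 down and 3 up of 13, median -0.71, camera adjusted p = 2.63e-05, but adjusted p = 0.119 with an estimated correlation), and the members that rose were Cxcl12 (0.88), Cxcl17 (0.69) and Cxcl13 (0.31). All 8 comparisons shared the same arrays, so these families add no new samples.

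A hypothesis was that mice carrying the disrupted Hmox1 allele also carry DNA of another strain around it, which would concentrate called genes there. Within 5 Mb of Hmox1, 24.3% of 107 genes were called in the averaged HO1 comparison, while windows around other genes held from 19.6% to 41.1% (5th to 95th percentile), so called genes were not concentrated there. The same was asked of Fmr1, whose signal was lower in every array labelled HO1-/-, and its window held 22.6% of 53 genes against 15.1% to 45.3%, so they were not concentrated there either. A further hypothesis was that Setdb2 and Phf11c rose with HO2 shRNA as part of a change of their stretch of chromosome. The other 12 genes within 1 Mb of Setdb2 had a median of 0.0916, against 3.24 for Phf11c and 2.75 for Setdb2, so the genes around did not rise by as much. Of these, 5 passed, within the range of windows around other genes (8.33% to 58.3%, here 41.7%). Phf11d and Cab39l, the genes on either side of the pair, rose (0.43 and 0.43), as did Atp8a2 (0.40) and Mtmr6 (0.13), while Nupl1 fell (-0.34).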
